A study of Danio rerio with 12 samples.

How the data were processed

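Total RNA of zebrafish (Danio rerio) was sequenced in 12 libraries, 2 replicates in each of 6 groups. Per the labels, 4 groups are embryos at the shield stage, 6 h after fertilization: wild type (strain Tu), anp32e null (strain NHGRI), maternal null and paternal null (both crosses of Tu and NHGRI, in which the mother or the father carried the mutation). The fifth group is embryos at the earlier sphere stage that had received Anp32e protein, and the other group bears the label sperm of anp32e null fish. No strain is given for either. RNA was extracted with Trizol and SDS and made into stranded TruSeq libraries after removal of ribosomal RNA with Ribo-Zero Gold, per the labels.

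The deposited table holds read counts per Ensembl gene, with no normalization. The authors used Novoalign 2.8 and DESeq2 per the submitters' processing notes, and they left out genes below a minimum: the lowest maximum over the libraries is 10 counts. The read counter, the annotation release, the strand setting of the counting and the role of each tool are not given in the sources used here. Coordinates are headed Zv10 in the table. It holds 22737 genes, of which 20669 (90.9%) were given a symbol by their Ensembl identifier; 2068 had none, and 2828 identifiers share a symbol with another and are named by their identifier where needed. For 50 genes the counts equal those of another gene in every library. All 12 value columns were matched to their labels.

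Total counts per library were 25.1 and 13.5 M in wild type, 25.7 and 21.2 M in null, 18.5 and 23.6 M in maternal null, 21.2 and 24.0 M in paternal null, 24.1 and 23.0 M in injected embryos, and 47.7 and 38.7 M in the libraries labelled sperm. Levels are in CPM, counts scaled to a common library total; a group's level is its summed counts over its summed totals unless a mean and SD are given. Counting intervals are 95% intervals (Wilson for a share of a library, exact Poisson for 1 to 3 counts), and a gene at 0 counts over both libraries of a group was set to a floor of 3 counts over the group, so that its fold is a lower bound. These intervals and floors cover counting error only.

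Counts were tested in edgeR 4.0.16 under R 4.3.3 by the robust quasi-likelihood F test, with TMM scaling, the filterByExpr filter by group and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The 6 comparisons among shield embryos came from a single fit of the 8 shield libraries (4 residual degrees of freedom, common biological coefficient of variation 0.167), and the comparisons with the injected embryos and with the libraries labelled sperm from a fit of all 12 (6 residual degrees of freedom). The shield groups form a 2 by 2 layout of the mother's and the father's genotype, from which the difference by mother and the interaction of both parents were tested.

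The replicates were then checked against counting noise over genes with at least 20 counts in the pair. In the null, maternal null, paternal null and injected groups the 2 libraries of a group differed by little more than counting noise (chi-square per degree of freedom 1.05, 1.16, 1.17 and 1.05), as repeated sequencing of 1 RNA sample would. In wild type and in the libraries labelled sperm the ratio was 95.2 and 42.9. A second fit, chosen after seeing the data, therefore summed each near-identical pair into 1 sample (5 shield samples with 1 residual degree of freedom, common coefficient of variation 0.344; 8 samples with 2 residual degrees of freedom for all groups). In that fit of the shield samples the spread comes from the wild-type libraries alone. The words rose and fell are used only of genes past the threshold in the same direction in both fits. Other genes are given as higher or lower in the fit of every library. Each SE is from the fit of every library, which takes near-identical pairs as replicates and so can understate the spread between samples. An SD over such a pair covers little more than counting noise. The deviations of same-numbered libraries had correlations between 0 and 0.02 over 6 pairs of groups, but each pair of groups holds a near-identical pair of libraries, so this does not tell whether the numbers pair libraries. A replicate block was used only as an alternative.

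Both fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Near-identical pairs were simulated with the spread of the fit with 1 sample per pair, which among shield samples comes from wild type alone. For null against wild type with independent libraries, the fit of every library recovered 46% and 100% of these and called 6 of 18966 unchanged genes. With near-identical pairs it recovered 64% and 98% but called 4513 unchanged genes (24%), while the fit with 1 sample per pair recovered 0% and 17% and called 1. For the comparison with the libraries labelled sperm the shares of unchanged genes called were 13% and 0.0095%, with 97% and 59% of 4-fold changes recovered, and for the injected embryos 12% and 0.0095%, with 97% and 57%. The 24% is no rate for every real comparison: maternal and paternal null against wild type called 1151 and 1346 genes in all, fewer than these 4513. A simulated list of 40 genes moved together was called in each of these simulations, and 0 of 20 random lists were. Genes varied independently of each other in the simulations. They do not test lists whose members vary together, such as the enveloping layer (estimated correlation 0.665).

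The comparisons, tests, 22 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The fit with 1 sample per pair and the omission of the libraries labelled sperm were added afterwards. The rule names anp32e first; then, for the 3 comparisons with wild type among shield embryos and for maternal null against paternal null, the 10 genes with the largest change each way that passed the threshold, did not overlap between the groups' libraries, reached 2 CPM in the higher group and had a given symbol rather than a clone name. For the other comparisons it names 5 each way, and from every list up to 4 members with the smallest p. Other genes named here were chosen after their values were seen. List members were matched by symbol, by a RefSeq synonym, or by the human symbol without its paralog letter. The lists, 940 members written and 791 matched, cover the anp32 family, the H2A.Z exchange and DNA methylation machinery, oocyte, germline, sperm, early zygotic, organizer, ventral, mesoderm, endoderm, enveloping layer, yolk syncytial layer, later patterning, differentiated tissue, p53, stress, interferon, plasma, testis somatic, chromatin repressor and histone genes.

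Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated one, and with fry, which asks whether a list moves on balance one way and compares it with no other genes; p-values were adjusted over the lists of a comparison. The estimated correlation comes from the residuals of the fit of every library. Among shield libraries it therefore rests mainly on the difference between the wild-type libraries. The list tests also take near-identical pairs as replicates. List members were also adjusted over the list alone. Effects were correlated across genes, beside 20 simulated sets of unchanged groups with the same shared wild-type libraries. Alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, no filter and at least 5 CPM in 2 libraries. Others were a log2 fold change of at least 1, a replicate block, leaving out each library in turn and fitting only the groups compared. Among shield libraries, leaving out a wild-type library or fitting only the crosses leaves near-identical pairs as the only replicates. The counts of genes then rest on little more than counting noise.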

Results

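RNA of 12 zebrafish libraries was counted per gene: 8 from shield-stage embryos (wild type, anp32e null, maternal null and paternal null, 2 each), 2 from sphere-stage embryos that had received Anp32e protein and 2 labelled as sperm of null fish. Anp32e is a histone chaperone known for removing the variant H2A.Z from chromatin, and the series concerns nucleosomes that hold DNA methylation off between germline and embryo. Totals ran from 13.5 to 47.7 M counts. The first principal component of the shield libraries held 50.7% of their variance and set the null libraries (94.9 and 95.6) apart from wild type (-64.7 and -23.8), with maternal null at -16.4 and -16.3 and paternal null at -35 and -34.2. The wild-type libraries differed from each other at 10736 of 17620 genes, those of the null group at 1 of 17713. The share of counts on the mitochondrial chromosome was 1.82% and 1.96% in wild type, 1.72% and 1.71% in null, 2.4% and 2.42% in maternal null and 3.08% and 3.12% in paternal null. Over genes with an mt- symbol alone it was 1.58% and 1.1%, 1.54% and 1.52%, 1.09% and 1.12%, and 1.9% and 1.94% in the same order. Null and wild-type shield embryos differ in strain as well as genotype, the 2 crosses combine both strains, and no strain is given for the injected embryos.

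The anp32e transcript itself (ENSDARG00000054804, chromosome 19 from 42758985 to 42772378) was nearly lost from null embryos. It stood at 2730 ± 628 CPM in wild type (SD, n = 2; 2280 and 3170) and at 80.8 ± 0.523 CPM in null embryos (SD over 2 near-identical libraries), which is 2.96% of wild type. The fall of -5.07 ± 0.27 on the log2 scale (SE) had an adjusted p of 0.00019 with every library and 3.9e-05 with 1 sample per pair. Maternal null embryos held 44.7% and paternal null embryos 51.9% of the wild-type level, 1220 ± 10.4 and 1420 ± 5.35 CPM (SD over 2 near-identical libraries each). Their log2 changes were -1.16 and -0.97, with adjusted p-values of 0.037 and 0.055 in the fit of every library and 1.0 for both with 1 sample per pair, and the crosses differed from each other by -0.19 (adjusted p = 0.67). Sphere embryos that had received the protein held 983 ± 5.2 CPM (SD over 2 near-identical libraries), 36% of the wild-type shield level. The libraries labelled sperm had 11 and 12 anp32e counts, or 0.231 (95% Wilson interval 0.129 to 0.413) and 0.31 CPM (0.177 to 0.541). Its relatives anp32a and anp32b stood at 702 and 1360 CPM in wild type and 856 and 1390 CPM in null embryos (adjusted p = 0.46 and 0.99).

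**Figure D1:**
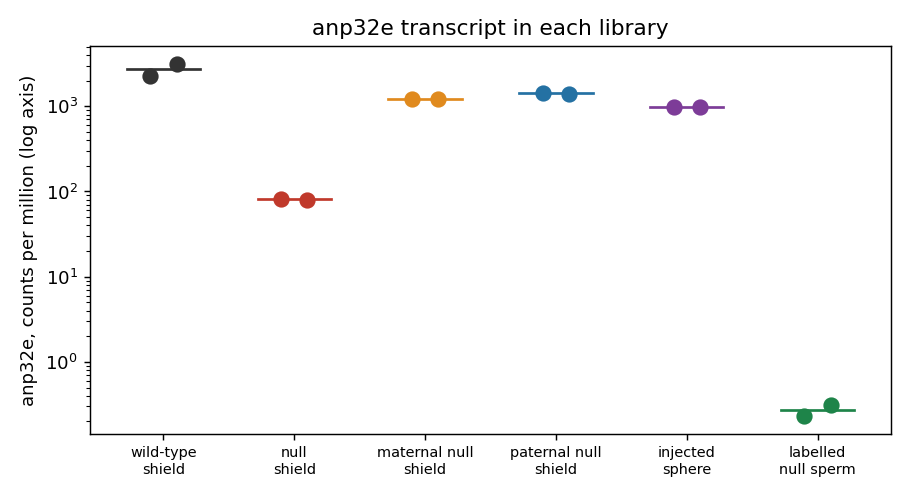
Level of the anp32e transcript in CPM on a log axis, where each point is a library and each bar a group mean. Null embryos sit near 80.8 and wild type near 2730, with maternal null at 1220 and paternal null at 1420.

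Null against wild type asks what loss of Anp32e from both parents does to the gastrula transcriptome, with the strain difference included. By the check of replicates the null libraries stand for 1 sample. Several genes of the outer epithelium, of the yolk syncytial layer and of neural and axial patterning rose in null embryos, and a few germline and oocyte genes fell. As sets these lists were called with a preset correlation only (adjusted p = 0.554 for the enveloping layer, 0.0873 for the yolk syncytial layer, 0.554 for later patterning and 0.351 for both germline and oocyte genes with an estimated correlation). agr1, a gene of mucus-secreting epithelium, rose 12.2-fold from 6.39 to 77.9 CPM (log2 fold change 3.70 ± 0.13 SE, 2 libraries per group, near-identical in null). The genes krt17, krt99 and anxa1b of the same layer rose 6.19-, 7.69- and 5.42-fold. apoa1a and tfa, which encode an apolipoprotein and transferrin, rose 7.12- and 5.71-fold. piwil1 and piwil2, the Argonaute proteins of the piRNA pathway, fell 4.88- and 5.2-fold. The maternal helicase subunit gene mcm3l fell 5.41-fold.

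Of 29 enveloping layer genes tested, 18 were higher in null embryos, 1 was lower and 10 did not pass. Adjusted over the list alone these were 18 and 1, and 10 rose in both fits, among them cyt1l and anxa1c. The list as a set was higher (median log2 1.53; camera, adjusted p = 1.15e-08), a call not kept with the correlation estimated from the data (adjusted p = 0.554 with an estimated correlation). Of 25 yolk syncytial layer genes, 18 were higher and 2 lower with 5 not passing, the same 18 and 2 adjusted over the list alone. In both fits 8 rose, such as pla2g12b (5.29-fold) and an afp4 copy (ENSDARG00000041490, 5.81-fold). The median was 1.43 (camera, adjusted p = 1.31e-06; adjusted p = 0.0873 with an estimated correlation). The 6 liver and plasma genes tested share apoa1a, apoa2 and tfa with that list: 4 were higher, 1 lower and 1 did not pass, also adjusted over the list alone. The plasma protein gene fetub rose 4.38-fold (camera, adjusted p = 0.0871).

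Among 54 factors of later patterning, 22 were higher, 4 lower and 28 did not pass (24 and 6 adjusted over the list alone). The 7 that rose in both fits were pax6, which patterns eye and forebrain (4.75-fold), a foxb1 copy (ENSDARG00000053650, 8.28-fold), the hindbrain gene hoxb1b, hoxb8, gbx1, phox2a and neurog1. The median was 1.31 (camera, adjusted p = 0.0019; adjusted p = 0.554 with an estimated correlation). hoxb1b differed between the wild-type libraries, 0.239 and 3.11 CPM, against 28.7 and 28.2 CPM in null. Of 30 ventral and epidermal genes, 11 were higher, 4 lower and 15 did not pass (12 and 4 adjusted over the list alone); tp63, the master regulator of epidermis, rose 4.6-fold, and tfap2a rose with it (camera, adjusted p = 0.046; adjusted p = 0.407 with an estimated correlation). tbx6, a gene of presomitic mesoderm, rose 9.29-fold from 0.569 CPM. The mix-type homeobox gene sebox of early mesendoderm fell to 8.36 CPM from wild-type levels of 216 and 35.1 CPM.

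Of 50 germline and meiosis genes, 30 were lower, 3 higher and 17 did not pass (32 and 3 adjusted over the list alone), with piwil1, piwil2 and stk31 falling and sycp1, a synaptonemal complex gene, rising in both fits (median -0.99; camera, adjusted p = 2.6e-06; adjusted p = 0.351 with an estimated correlation). Of 46 oocyte genes, 29 were lower, 1 higher and 16 did not pass (30 and 2 adjusted over the list alone). The genes mcm3l, cldnd, wee2 and the egg coat gene zp3c fell in both fits (median -0.74; camera, adjusted p = 5.63e-05; adjusted p = 0.351 with an estimated correlation). fry gave adjusted p-values of 0.00136 for the germline list, 0.00204 for the oocyte list, 0.00249 for the enveloping layer and 0.000222 for the yolk syncytial layer. It did not single these lists out: it gave 0.00249 for testis somatic genes, 0.00563 for stress genes, 0.00873 for ventral genes, 0.012 for plasma genes and for chromatin repressors, 0.0138 for later patterning genes and 0.0245 for differentiated tissue genes.

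Camera did not call the other lists. Of 24 H2A.Z and exchange genes 3 were lower and 21 did not pass (1 lower adjusted over the list alone), mrgbp at -0.74 ± 0.13 having the smallest adjusted p, 0.0069. Of 24 DNA methylation genes 3 were higher and 2 lower (1 lower adjusted over the list alone); dnmt3b stood at 0.83 with an adjusted p of 0.021, and this list's median of -0.11 was of the opposite sign to its camera direction, as was the endoderm list's -0.03. Higher and lower counts were 9 and 8 of 68 sperm and flagellum genes (7 and 7 adjusted over the list alone), 8 and 9 of 46 early zygotic genes (8 and 9), 7 and 6 of 27 organizer genes (9 and 6). They were 11 and 6 of 40 mesoderm genes (11 and 6), 2 and 4 of 18 endoderm genes (0 and 4), and 11 and 8 of 40 differentiated tissue genes (11 and 8). They were 7 and 5 of 28 p53 targets (9 and 6), 9 and 10 of 49 stress genes (9 and 10), 4 and 5 of 26 interferon genes (4 and 5), 5 and 2 of 12 testis somatic genes (6 and 2), 6 and 2 of 35 chromatin repressors (2 and 0), and 2 and 0 of 8 histone genes (2 and 0).

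The largest changes of the named genes were of transcripts with few or no counts in 1 of the 2 groups. The calpain gene capn8 stood at 13.1 CPM in wild type (18.9 and 2.44 in its libraries) and had no count in null embryos, at least 206-fold lower. The genes map1lc3cl, rnd2, dhrs11b.2, vmo1a, plxnb2a.2, btr32 and znf1106 also had none, at least 69.6-, 56.6-, 46.1-, 57-, 45.7-, 41.3- and 32.4-fold lower. The wild-type libraries differed for vmo1a (5.09 and 0.961 CPM) and plxnb2a.2 (3.78 and 1.33 CPM), so that these bounds rest mainly on replicate 1. znf1062, a zinc finger gene, fell 209-fold (95% counting interval 58 to 1730). In the other direction mchr1, a receptor of melanin-concentrating hormone, rose 171-fold from 1 wild-type count (interval 30.6 to 6740), the kinase gene stk33 rose 68.4-fold (23.4 to 332) and prrt4a 61-fold (16.9 to 503). The neural transcription factor genes pou3f1 and fezf2 rose 30.7- and 25.7-fold. The genes brinp3, abi3bpa, nlrc9 and fkbp16 rose 29-, 30.7-, 25.4- and 24.4-fold.

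**Figure D2:**
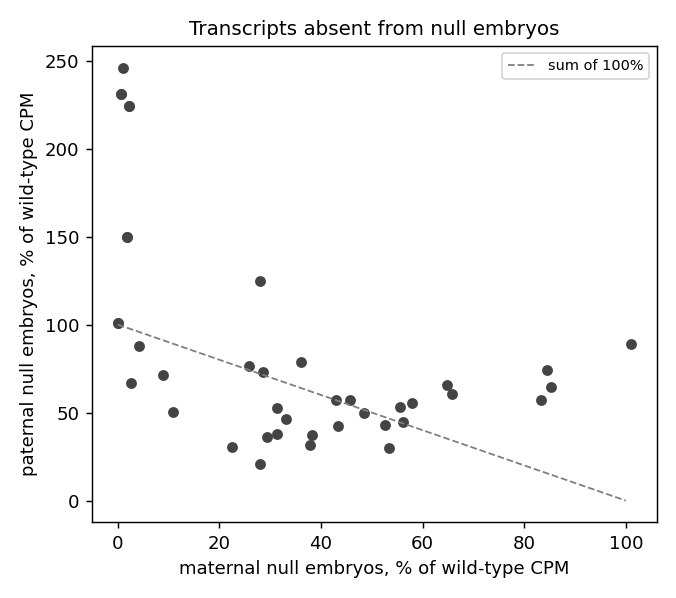
Levels in maternal null (x axis) and paternal null embryos (y axis), in percent of wild type, of the 40 transcripts with at most 3 counts over both null libraries, where each point is a transcript and the line marks a sum of 100%. The medians are 31.4% in the maternal and 62.7% in the paternal cross.

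edgeR called 6938 of 19166 genes with every library as a replicate, 3222 higher and 3716 lower. With 1 sample per near-identical pair it called 1052, and 470 rose and 546 fell in both fits. The first count was 11393 and 14657 without wild-type replicate 1 or 2, and 2654 and 2798 without null replicate 1 or 2.

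**Figure D3:**
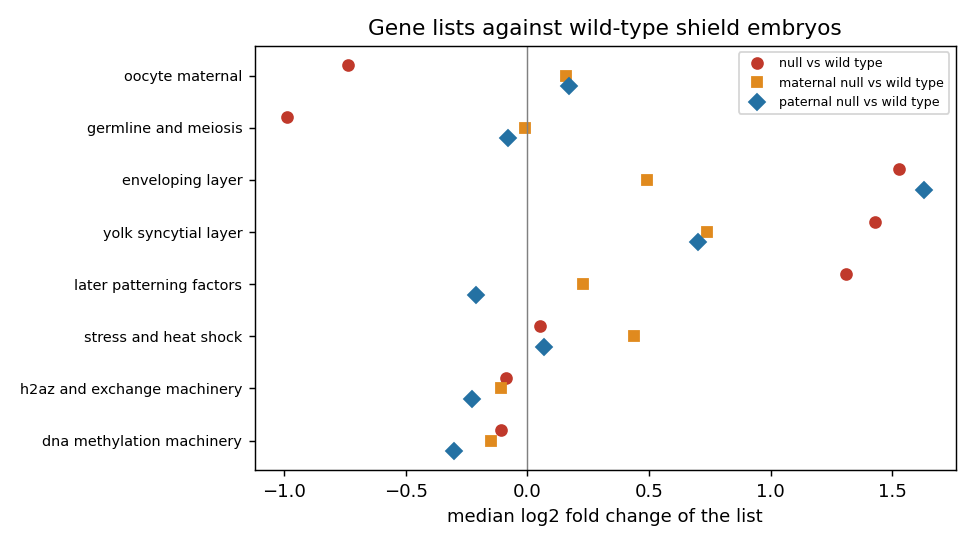
Median log2 fold change of gene lists against wild-type shield embryos in null, maternal null and paternal null embryos, where each marker is the median over the list's tested genes. In null embryos the enveloping layer stands at 1.53, the yolk syncytial layer at 1.43 and the germline list at -0.99.

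Maternal null against wild type asks what is changed when the egg, but not the sperm, came from a null fish. The strain of the egg differed too. By the check of replicates the maternal null libraries stand for 1 sample, whose own state cannot be told from an effect of the null egg. Heat shock genes were far higher: hspa2 and hsp70l rose 86.7- and 83.8-fold, to 11.2 and 19.5 CPM. The genes hsp70.3 and hsp70.1 rose 42.7- and 41.6-fold (log2 fold change of hsp70.3 5.48 ± 0.17 SE, 2 libraries per group, near-identical in maternal null). The inducible chaperone gene hsp90aa1 rose 22.4-fold from 13.1 to 293 CPM. Type I collagen genes also rose, col1a1 by 8.04-fold and col1a2 by 5.72-fold, as did sycp1 (15.4-fold), the collagen hydroxylase gene p4ha3 (17.2-fold) and stk33 (35.2-fold, interval 12.1 to 171). rflnb and itgam.1, which encode an actin-binding refilin and an integrin subunit, fell 46.8- and 41.5-fold.

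Of 49 stress genes, 14 were higher, 35 did not pass and 6 rose in both fits, including an hspa8 copy (ENSDARG00000037403, 40.6-fold) and hsp90aa1.1. Adjusted over the list alone 21 were higher and 1 lower. Camera called the list higher (adjusted p = 5.62e-09, and 0.0324 with an estimated correlation). Of 25 yolk syncytial layer genes, 8 were higher, 1 lower and 16 did not pass (14 and 1 adjusted over the list alone; camera, adjusted p = 9.79e-07, and 0.0443 with an estimated correlation); cebpa and the yolk layer regulator mxtx1 stood 2.24- and 2.16-fold above wild type and did not pass with 1 sample per pair. Of 29 enveloping layer genes, 10 were higher and 19 did not pass, also over the list alone, and icn rose in both fits (camera, adjusted p = 1.98e-07; adjusted p = 0.544 with an estimated correlation). Smaller shifts upward were called for p53 targets (2 of 28 higher, 4 adjusted over the list alone, plk3 at 0.98; adjusted p = 0.000495, and 0.294 with an estimated correlation), early zygotic genes (3 of 46, also over the list alone; 0.00773, and 0.148 with an estimated correlation) and ventral genes (2 of 30, also over the list alone; 0.00726, and 0.213 with an estimated correlation).

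Fewer transcripts also came from tars3, a threonyl-tRNA synthetase gene (16.3-fold), from the extracellular matrix genes ncan and hapln4 (15.4- and 10.8-fold), and from cacnb4b, c7b, msraa, gsk3bb and pgghg (21.4-, 12.5-, 10.5-, 10.4- and 10.4-fold), each of which fell in both fits. Null embryos, whose mothers were also null, held 0.128 CPM of rflnb, 0.192 CPM of itgam.1 and 1.75 CPM of hapln4, while paternal null embryos held 20.2, 9.06 and 37.5 CPM.

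edgeR called 1151 genes, 639 higher and 512 lower, with every library, and 120 with 1 sample per pair; 73 rose and 41 fell in both. The first count was 9735 and 11257 without wild-type replicate 1 or 2, and 62 and 45 without maternal null replicate 1 or 2.

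**Figure D4:**
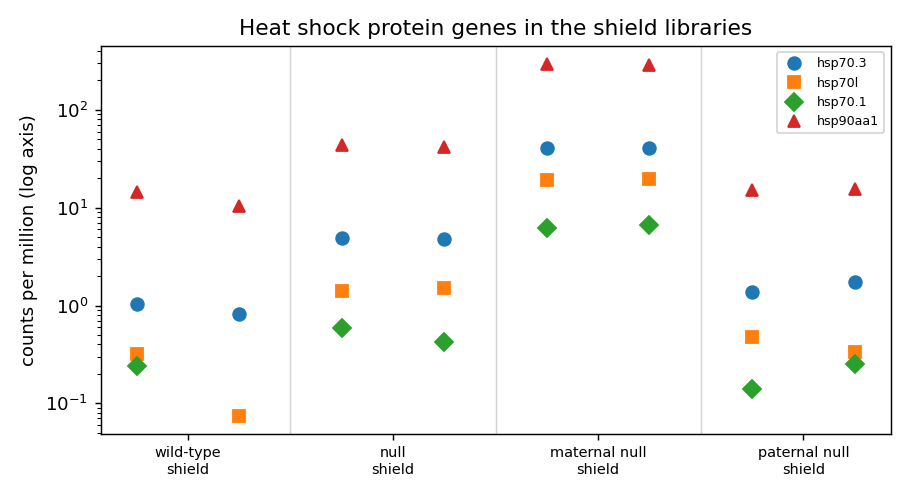
CPM, on a log axis, of heat shock protein genes in each of the 8 shield libraries, where each point is a library. hsp90aa1 stands at 293 in maternal null embryos, against 13.1 in wild type, 42.8 in null and 15.3 in paternal null.

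Paternal null against wild type asks the same of a null sperm with a wild-type egg. The strain of the sperm differed too, and the paternal null libraries likewise stand for 1 sample. The enveloping layer was again higher: krt99 rose 4.97-fold from 80.5 to 400 CPM (log2 fold change 2.40 ± 0.13 SE, 2 libraries per group, near-identical in paternal null). cyt1l rose 4.6-fold and agr1 rose from 6.39 to 28.4 CPM. Of 29 enveloping layer genes, 16 were higher and 13 did not pass (24 higher and 1 lower adjusted over the list alone), with a median of 1.63 (camera, adjusted p = 9.08e-18; adjusted p = 0.443 with an estimated correlation). wizb, a zinc finger gene, fell 44.4-fold from 4.92 to 0.111 CPM. The innate immune genes nlrc9, nlrc8 and ifi44f4 rose 12.9-, 6.8- and 10.9-fold, and olfcb1, drd4a, slc6a16a, cacna1ha and dmtn rose 10.1-, 9.74-, 7.26-, 6.18- and 6.57-fold.

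Heat shock genes differed less here: hsp70.3 was 1.64-fold above wild type with an adjusted p of 0.076, and 1 of 49 stress genes, nqo1, was higher (1 adjusted over the list alone). Of 25 yolk syncytial layer genes, 7 were higher and 18 did not pass (12 and 3 lower adjusted over the list alone; camera, adjusted p = 0.000816, and 0.245 with an estimated correlation). Camera also called the DNA methylation list lower (1 of 24 higher; 1 higher and 2 lower adjusted over the list alone; adjusted p = 0.0126, and 0.27 with an estimated correlation) and the H2A.Z list lower, with all 24 members short of the threshold (median -0.23; adjusted p = 0.0422, and 0.487 with an estimated correlation). It called oocyte genes higher (3 of 46, buc at 2.3-fold; 4 higher and 1 lower adjusted over the list alone; adjusted p = 0.0264), p53 targets (3 of 28; 4 adjusted over the list alone; 0.0303) and plasma genes (5 of 6 adjusted over the list alone; 0.0404), each at 0.487 with an estimated correlation. The genes heatr4, lrrtm2 and gsk3bb stood 8.93-, 5.37- and 4.89-fold below wild type in the fit of every library and did not pass with 1 sample per pair.

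edgeR called 1346 genes, 901 higher and 445 lower, with every library, and 50 with 1 sample per pair; 39 rose and 5 fell in both. The first count was 10343 and 10682 without wild-type replicate 1 or 2, and 18 and 6 without paternal null replicate 1 or 2.

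Maternal null against paternal null sets the reciprocal crosses side by side: both combine the same strains, and they differ in which parent was null and in the strain of the egg. By the check of replicates each cross stands for 1 sample. The words rose and fell therefore rest here on no measured spread between samples within a cross. The heat shock genes rose in the maternal cross, hsp70l 48.9-fold (log2 fold change 5.61 ± 0.28 SE, 2 near-identical libraries per group) and the hspa8 copy 133-fold. The chemokine gene cxcl18b rose at least 127-fold and mhc2dab at least 50.1-fold, both from no counts. So did cxcl8a, 302-fold from 1 count (interval 54.3 to 11900), and cd74a, 52-fold. The genes col1a1 (64.8-fold) and muc5.2, a mucin gene (56.5-fold, 19.3 to 274), rose as well. Wild type lay between the crosses for cxcl18b, mhc2dab, cxcl8a, cd74a, col1a1 and muc5.2. cd74a stood at 2.15 CPM in wild type, 4.61 in maternal null and 0.0886 in paternal null, so its fold comes largely from the low paternal level. rflnb fell 85.1-fold, itgam.1 31.8-fold and gabrd, a GABA receptor subunit gene, 20.7-fold, as did ncan, pgghg, bbs4, tars3, nsmf and msraa by 10.7- to 13.1-fold.

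Of 49 stress genes, 17 were higher, 3 lower and 29 did not pass (23 and 3 adjusted over the list alone), and 7 rose in both fits, fosb and fosl1 among them (camera, adjusted p = 1.38e-07, and 0.0482 with an estimated correlation). Of 29 enveloping layer genes, 14 were lower, 3 higher and 12 did not pass (22 and 3 adjusted over the list alone), and icn2 rose in both fits (median -1.24; camera, adjusted p = 5.94e-09; adjusted p = 0.569 with an estimated correlation). Early zygotic, ventral and chromatin repressor genes were called higher as sets, with 4 and 3 of 46, 3 and 2 of 30 and 2 and 0 of 35 members higher and lower (8 and 4, 7 and 2, 2 and 0 adjusted over the list alone). The adjusted p-values were 0.0226, 0.0184 and 0.0294, and 0.24 for each with an estimated correlation. With 1 sample per pair each cross is 1 sample and the spread is that of wild type, a group outside this comparison. The counts of genes below are to be read with that limit. edgeR called 1778 genes, 702 higher and 1076 lower, with every library, and 104 with 1 sample per pair; 62 rose and 38 fell in both. The first count was 143 and 79 without maternal null replicate 1 or 2, and 168 and 135 without paternal null replicate 1 or 2.

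The difference by mother compares embryos of null mothers (null and maternal null) with embryos of wild-type mothers, over both fathers. Embryos of null mothers held more stk33 (log2 difference 5.45 ± 0.45 SE with every library as a replicate, 4 libraries per side), hsp70l (4.16 ± 0.22), mchr1 (4.25 ± 0.27) and p4ha3 (4.03 ± 0.2). They held less rflnb (-6.26 ± 0.4), itgam.1 (-5.32 ± 0.36), ncan (-4.02 ± 0.21) and plxnb2a.2. The value of plxnb2a.2 (-5.82 ± 0.59) has no firm size, since null embryos had no count of it. Each rose or fell in both fits. anp32e was lower by -2.63 ± 0.17. The hsp70l difference came mainly from maternal null embryos, at 19.5 CPM. Null embryos held 1.45 CPM, wild type 0.233 and paternal null 0.399.

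Of 25 yolk syncytial layer genes, 16 were higher and 9 did not pass (19 higher and 1 lower adjusted over the list alone; camera, adjusted p = 7.78e-07, and 0.0753 with an estimated correlation). Of 50 germline genes, 25 were lower, 4 higher and 21 did not pass (30 and 4 adjusted over the list alone; adjusted p = 4.07e-06, and 0.196 with an estimated correlation). Of 46 oocyte genes, 17 were lower and 29 did not pass (19 lower adjusted over the list alone; 0.000851, and 0.196), with mcm3l at -2.11 ± 0.093 and wee2 falling in both fits. Maternal null against wild type did not show this: 2 oocyte genes were higher and 1 lower (3 and 1 adjusted over the list alone; median 0.16; camera, adjusted p = 0.18), and 1 germline gene was higher and 3 lower (1 and 4 adjusted over the list alone; median -0.01; 0.636). Stress genes were 12 higher and 2 lower of 49 (13 and 2 adjusted over the list alone; adjusted p = 0.00125, and 0.123 with an estimated correlation), later patterning genes 15 and 3 of 54 (also over the list alone; 0.00125, and 0.319). As a set the stress list was not called by camera in null against wild type (median 0.05, adjusted p = 0.639). There 9 of 49 stress genes were higher and 10 lower. Heat shock genes named for maternal null still stood above wild type in null embryos. These were hspa2 at 1.26 against 0.129 CPM, hsp70.3 at 4.88 against 0.957 CPM and hsp90aa1 at 42.8 against 13.1 CPM. Ventral genes were 8 higher of 30 (11 adjusted over the list alone; 0.00307, and 0.196). The yolk syncytial, later patterning and ventral genes counted here, and the lower germline genes, passed in the fit of every library only. For the enveloping layer, 11 of 29 were higher, also over the list alone, and icn and icn2 rose in both fits. Camera called the list higher (adjusted p = 0.0109, and 0.632 with an estimated correlation) though its median was -0.01 and its mean 0.32. edgeR called 5010 genes, 2264 higher and 2746 lower, with every library, and 496 with 1 sample per pair; 138 rose and 345 fell in both. The first count was 11086 and 13834 without wild-type replicate 1 or 2, and 2026 and 2090, 2148 and 2034, and 2078 and 2031 without replicate 1 or 2 of the null, maternal null and paternal null groups.

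The interaction asks whether the effects of both parents add up on the log scale. Several patterning factors were high only where both parents were null, among the shield groups: meis2b stood at 23.8 CPM in null embryos against 0.931, 0.689 and 0.554 CPM in wild type, maternal null and paternal null, hoxb1b at 28.5 against 1.24, 0.737 and 1.04 CPM, and pax6 at 9.7 against 2.04, 1.05 and 0.488 CPM (log2 interaction 6.02 ± 1.4, 5.73 ± 1.3 and 5.24 ± 0.35 SE). The same held for kctd15 (5.27 ± 0.4) and lbx2 (5.15 ± 1.3). meis2b and hoxb1b also differed between the wild-type libraries, meis2b standing at 0.159 and 2.37 CPM. In the other direction map1lc3cl, rnd2 and plxnb2a.2 lacked counts in null embryos and were present in the other 3 groups. The gene mxtx2, a yolk layer regulator, and hsp70l (-4.57 ± 0.52) were lower in null embryos than the 2 crosses would add up to.

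As sets, oocyte genes (20 lower and 1 higher of 46; 28 and 1 adjusted over the list alone; camera, adjusted p = 1e-07, and 0.161 with an estimated correlation), germline genes (19 and 2 of 50; 26 and 3 adjusted over the list alone; 3.22e-05, and 0.255), stress genes (16 and 1 of 49; 22 and 3 adjusted over the list alone; 0.000214, and 0.15) and p53 targets (6 lower of 28; 7 adjusted over the list alone; 0.00256, and 0.257) had lower interactions. The enveloping layer was lower too, at 3 of 29 (2 adjusted over the list alone). Camera gave it an adjusted p of 0.0061, and 0.646 with an estimated correlation. Except among stress and later patterning genes, the list members counted in this paragraph passed in the fit of every library only. Later patterning genes (7 higher and 4 lower of 54; 9 and 5 adjusted over the list alone; 0.0166, and 0.507), DNA methylation genes (3 and 1 of 24; 5 and 1 adjusted over the list alone; 0.0352, and 0.255) and sperm genes (7 and 2 of 68; 5 and 2 adjusted over the list alone; 0.0479, and 0.255) were higher. edgeR called 3261 genes, 1304 higher and 1957 lower, with every library, and 67 with 1 sample per pair, 56 of them in both (14 higher, 42 lower). The first count was 12259 and 11273 without wild-type replicate 1 or 2, 8 and 6 without paternal null replicate 1 or 2, and 0 without a null replicate (4752 and 4876 genes at an unadjusted p under 0.05) or a maternal null replicate (4890 and 4846).

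Null fish are represented both by shield embryos and by the libraries labelled sperm, which differ in tissue, stage and content. The libraries labelled sperm were rich in oocyte transcripts. zar1, a gene needed at the egg-to-embryo transition, was 206-fold above null embryos at 1220 CPM. Its log2 fold change was 7.62 ± 0.18 (SE, 2 libraries per group, near-identical in null). The egg coat genes zp3a.1, zp3e and zp3b reached 3070 and 4130, 2970 and 3780, and 3010 and 3420 CPM, and buc, which organizes the Balbiani body of oocytes, 1710 and 1620 CPM. Of 46 oocyte genes, 41 rose, 4 fell and 1 did not pass in either fit, the same adjusted over the list alone (camera, adjusted p = 9.07e-12, and 0.0441 with an estimated correlation); stm fell 7670-fold. The list of sperm and flagellum genes was mixed, with 44 higher, 27 lower and 12 not passing of 83, also over the list alone (30 rose and 18 fell in both fits; camera, adjusted p = 0.555). The median over this list was 1.47 and 1.68 CPM in these libraries, against 541 and 554 CPM over the oocyte list.

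Genes of 7 embryonic lists were mostly lower there, while later patterning genes (40 higher and 32 lower of 89, also over the list alone; camera, adjusted p = 0.7) and differentiated tissue genes (23 and 22 of 54; 23 and 23 adjusted over the list alone; 0.947) went both ways. Early zygotic genes fell in 44 of 46 cases, organizer genes in 25 of 28, mesoderm genes in 35 of 40, ventral genes in 26 of 30, yolk syncytial genes in 24 of 25, enveloping layer genes in 26 of 31 and endoderm genes in 15 of 18, the same numbers adjusted over the list alone, with noto, a notochord factor, 2280-fold and tbxta 514-fold lower. Camera gave adjusted p-values of 3.14e-16, 3.81e-09, 2.49e-10, 1.4e-09, 1.14e-08, 3.49e-08 and 0.000187 for these lists, and 0.00104, 0.0041, 0.00627, 0.00627, 0.0041, 0.315 and 0.06 with an estimated correlation. Of 50 germline genes, 38 were higher and 8 lower (also over the list alone; 31 rose and 6 fell in both fits), with rnf17 and piwil2 63.5- and 20.4-fold higher (camera, adjusted p = 3.47e-06, and 0.06 with an estimated correlation). Of 8 histone genes, 6 fell (also over the list alone; 0.024, and 0.558). Testis somatic genes were 8 higher and 5 lower of 16 (also over the list alone; adjusted p = 0.831). Single genes at the extremes were foxr1 and snai3, at least 642- and 277-fold higher, setmar and slc34a1, at least 142- and 105-fold higher. At the other end were foxd5 and agr1, at least 5350- and 2240-fold lower, and hspb1 and tbx16, 30600- and 12100-fold lower. edgeR called 17090 of 21251 genes with every library, 8773 higher and 8317 lower, and 13752 with 1 sample per pair; 6529 rose and 6756 fell in both.

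**Figure D5:**
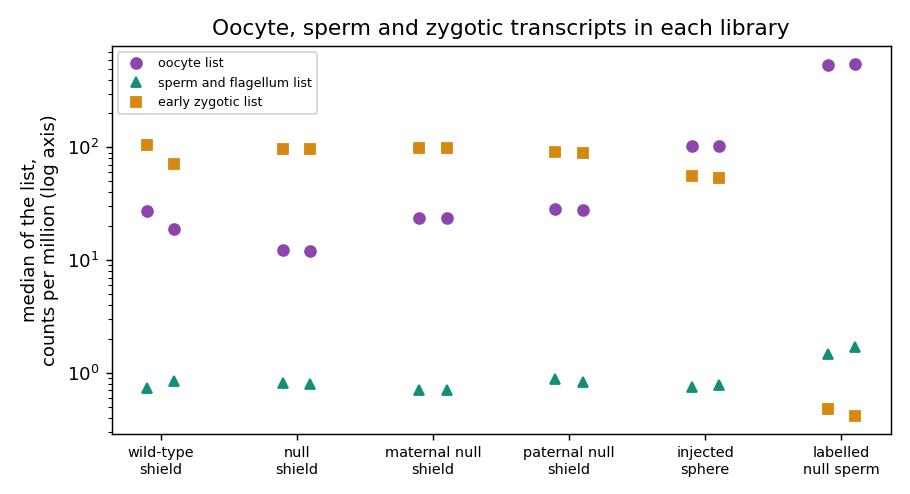
Median CPM over the oocyte, sperm and flagellum, and early zygotic lists in each of the 12 libraries, on a log axis, where each point is a library. In the libraries labelled sperm the oocyte list stands at 541 and 554 and the sperm list at 1.47 and 1.68.

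Injected sphere embryos against wild-type shield embryos differ in stage, in the injected protein and perhaps in strain, so that the comparison describes the difference between these groups alone. The earlier embryos held more maternal transcript, btg4 30.7-fold, buc 14.3-fold and dazl, a germ plasm gene, 9.34-fold higher, and less of the gastrula genes, such as the BMP regulator szl (34-fold lower), ripply1 (37.4-fold), the segmentation gene her1 (9.7-fold), tbxta (4.8-fold) and krt17 (12.9-fold). p53 targets were higher. bbc3, which promotes cell death, rose 22.6-fold from 10.5 to 238 CPM. Its log2 fold change was 4.29 ± 0.3 (SE, 2 libraries per group, near-identical in injected embryos). phlda3 rose 12.7-fold and sesn1 6.89-fold. With 1 sample per pair the spread here comes from the wild-type libraries and from those labelled sperm. Of 28 p53 targets, 19 were higher, 2 lower and 7 did not pass, also over the list alone, and 14 rose and 1 fell in both fits (camera, adjusted p = 3.49e-05; adjusted p = 0.0784 with an estimated correlation).

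Of 46 oocyte genes, 33 were higher and 6 lower, also over the list alone (26 rose and 2 fell in both fits; camera, adjusted p = 3.33e-06, and 0.144 with an estimated correlation). Of 50 germline genes these were 24 and 6 (also over the list alone; 0.0186, and 0.307). Lower in sphere embryos were 32 of 46 early zygotic, 22 of 28 organizer, 24 of 30 ventral, 29 of 40 mesoderm and 20 of 25 yolk syncytial genes (32, 22, 24, 30 and 21 adjusted over the list alone), of which 22, 14, 17, 23 and 12 fell in both fits. Each list held with an estimated correlation (adjusted p = 0.0171). Also called lower were 22 of 31 enveloping layer, 11 of 18 endoderm, 15 of 25 H2A.Z and 8 of 8 histone genes (the same adjusted over the list alone), at adjusted p = 0.336, 0.245, 0.394 and 0.336 with an estimated correlation. Higher in sphere embryos were 6 early zygotic, 3 mesoderm, 2 organizer, 2 ventral, 2 endoderm, 1 yolk syncytial and 1 enveloping layer genes (7, 3, 3, 2, 3, 1 and 1 adjusted over the list alone), with mxtx2 9.93-fold higher. The extremes were rims3, at least 41.1-fold higher, and sccpdha.2 (182-fold, interval 32.7 to 7210), lrit1 (136-fold, 24.5 to 5390) and rgs20 (77.2-fold). Lower were chst3 and lsm10, at least 34.1- and 30.4-fold lower, with krt91 and fthl28 186- and 118-fold lower. edgeR called 13540 genes, 6709 higher and 6831 lower, with every library, and 6514 with 1 sample per pair; 3562 rose and 2864 fell in both, and fitting only these 2 groups gave 8831.

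Effects were then correlated across 19166 genes, which are not independent replicates. Null against wild type and maternal null against paternal null, which share no library, had a Pearson correlation of 0.11 (Spearman 0.09), against 0 in simulated unchanged groups, and of 0.02 over genes of at least 5 CPM. The other 3 relations share the wild-type libraries, which alone give 0.35 in the simulation: null with maternal null reached 0.5 (covariance 0.479 against 0.168 simulated), null with paternal null 0.39 (0.359 against 0.166) and maternal with paternal null 0.34 (0.178 against 0.166). With a different wild-type library for each side, maternal with paternal null gave -0.07 and -0.01, null with maternal null 0.05 and 0.36, and null with paternal null -0.06 and 0.29. Of genes called against wild type in both crosses, 204 were higher in both, nlrc9 among them, 110 were lower in both and 37 went in opposite directions. Independence would give 30 and 11.9 and the simulated shared libraries gave 692.3 and 736.6. The simulation took its spread from the wild-type libraries alone and called more genes in both crosses than the data did, so it sets no scale for these counts. With 1 sample per pair 13 were higher in both and 0 lower.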

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

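The fit with 1 sample per near-identical pair was chosen after the results were seen. The interaction and the count over other splits of the libraries were chosen before. The effect of the mother's genotype differed with the father's genotype by a test of the difference itself: edgeR called 3261 genes for the interaction with every library as a replicate and 67 with 1 sample per near-identical pair, where the spread comes from the wild-type libraries alone. pax6 (log2 interaction 5.24 ± 0.35 SE) and hsp70l (-4.57 ± 0.52) passed in both. The test was on the log scale, where levels that simply add up between the parents also give an interaction. anp32e had a log2 interaction of -2.95 ± 0.33 SE. It stood at 2600 CPM in wild type, 1220 in maternal null, 1420 in paternal null and 80.9 in null embryos. The count with every library was not kept when any single library was left out. Null embryos are also the only shield group with both parents of strain NHGRI, so strain and mutation stay open as sources of the interaction, and no biological explanation of it was tested.

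The difference by mother was set against the other ways to split the 8 shield libraries 4 against 4. Of 35 splits, 1, the real one, gave as many genes (477 in a fit of 2 groups), and the highest other gave 349, the split of wild type and maternal null against null and paternal null, which follows the father's genotype. Only 3 of the 35 splits keep every group whole (477, 349 and 0 genes in edgeR), and the other 32 part libraries of a group, 3 of the 4 groups being near-identical pairs. With 3 comparable splits the share cannot fall under 0.05.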

How the results depend on the processing

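The fit with 1 sample per near-identical pair and the omission of the libraries labelled sperm were chosen after seeing the data. The other alternatives were chosen before. Of the values of named genes under alternatives, 3574 of 3833 kept their direction and side of the threshold and 259 lost the threshold. For gene lists these were 243 and 62 of 305, and for the anp32e level 58 of 72, with 11 weaker and 3 stronger. Counts of genes stayed within 1.5 times in 48 of 103 cases. DESeq2 size factors, the DESeq2 Wald test and no filter kept all 8 counts within 1.5 times, and so did the alternatives run for the libraries labelled sperm. For the changes below the cause was not tested. Exceptions by construction are tests of fewer genes or samples, and fits whose only replicates are near-identical pairs. Those fits are of the crosses alone and of shield libraries with a wild-type library left out. Their spread is little more than counting noise.

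A log2 fold change of at least 1 gave 4261 genes for null against wild type, 720 for maternal null, 846 for paternal null, 1130 for maternal against paternal null and 1938 by mother. At least 5 CPM, which tests fewer genes, gave 4507, 1158 and 3097 for null, maternal against paternal null and mother. The replicate block gave 568, 640 and 1119 for maternal null, paternal null and the crosses. One sample per pair gave 1052, 120, 50, 104, 496, 67 and 6514 in the order null, maternal null, paternal null, crosses, mother, interaction and injected. Only the groups compared gave 1876 for null, 10233 for the crosses, 8831 for injected, and 0 in edgeR for maternal and paternal null (2169 and 2362 at an unadjusted p under 0.05). It has no meaning for mother and interaction. Leaving out each library in turn, where a lone sample is assumed to vary like the other groups, gave 2654 to 14657 for null, 45 to 11257 for maternal null, 6 to 10682 for paternal null, 79 to 168 for the crosses, 2026 to 13834 by mother and 0 to 12259 for the interaction (edgeR; at least 4752 at an unadjusted p under 0.05). One sample per pair with a wild-type library left out has no residual degrees of freedom and was not run.

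The anp32e change in maternal null no longer passed with the replicate block (-1.14), with 1 sample per pair (-1.16) or without either maternal null library (range over all libraries left out -1.47 to -0.79). In paternal null it passed with the DESeq2 Wald test (-0.97) and without either wild-type library (range -1.27 to -0.58). For the interaction it no longer passed with 1 sample per pair (-2.97) or without any 1 of the null, maternal null or paternal null libraries (range -3.32 to -2.64).

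The DESeq2 Wald test and leaving out libraries were not run for the lists. With an estimated correlation, lists called went from 6 to 0 for null (camera), 6 to 2 for maternal null, 7 to 0 for paternal null, 5 to 1 for the crosses, 7 to 0 by mother, 8 to 0 for the interaction, 10 to 6 for the libraries labelled sperm and 12 to 5 for injected. 1 sample per pair gave 3 for paternal null and 2 for the crosses. The correlation of null with the crosses was 0.02 over genes of at least 5 CPM. With separate wild-type libraries it reversed for maternal with paternal null (-0.07 and -0.01) and null with paternal null (-0.06), and was 0.05 for null with maternal null. Depth limits what is seen at the floor of 3 counts, in 13.5 to 47.7 M counts per library.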

Other observations

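The tests of explanations in this part were chosen after the results were seen. The maintenance methyltransferase gene dnmt1 stood at 216 CPM in wild-type shield embryos, at 758 CPM in injected sphere embryos and at 2070 CPM in the libraries labelled sperm, which is 7.64-fold above null shield embryos. Of 25 DNA methylation genes, 7 were higher and 12 lower in the libraries labelled sperm than in null embryos (camera, adjusted p = 0.387), and 9 were higher and 10 lower in injected sphere than in wild-type shield embryos (adjusted p = 0.531).

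A group of 9 small transcripts on chromosome 20, from 3306064 to 3316290 and with u3 among them, had no counts in null embryos. They stood at 0% to 2.14% of the wild-type level in maternal null embryos and at 101% to 246% in paternal null embryos. Several pairs of them overlap nearly in full and have the same counts, so they are fewer than 9 independent signals.

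The libraries labelled sperm hold oocyte transcripts. The lower of their medians over 11 zona pellucida genes was 1270 CPM (1980 in the other), all 11 stood above 100 CPM in both, and the most abundant were zp3a.1, zp3b and zp3e. Sperm RNA as the main content is argued against by the sperm list, whose median reached at most 0.303% of the oocyte list's. Oocyte or ovary RNA, through another label or a mixture, is a candidate source by the zona pellucida value; shield embryos hold the same transcripts at lower levels (26.9 CPM in wild-type replicate 1). Which of these it was, and whether some sperm RNA is present, stays open. The share of counts on the mitochondrial chromosome was 0.1% and 0.08% in the libraries labelled sperm, against 1.72% and 1.71% in null embryos. What this low share tells of their content was not tested.

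Genes were split by their change from injected sphere to paternal null shield embryos, groups that differ in more than stage and of which the second shares a null father with null embryos. Of 1873 genes that rise between them, 69.3% were higher in null embryos, and of 1148 that fall, 63.8% were lower. The mean log2 CPM of the rising genes was 2.51 and 2.5 in null and 2 in both wild-type libraries, and that of the falling genes -0.57 in both null libraries and -0.09 and -0.73 in wild-type replicates 1 and 2. Paternal null stood at 2.54 for the rising genes, and in maternal null embryos 51.5% of the rising and 38.6% of the falling genes went the same way. Null embryos further along in development and a change at the same stage cannot be told apart, since stage was not measured apart from genotype and parent. A larger share of enveloping layer and yolk cells in the null sample also stays open: the later patterning list, which such cells would dilute, had a median of 1.31, but its members spread on both sides of 0 (quartiles -0.43 and 2.26). Strain was not separated either and stays open.

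Of 40 transcripts with at most 3 counts over both null libraries and at least 2 CPM in each wild-type library, with capn8, map1lc3cl and rnd2 among them, 22 stood at 20% to 80% of wild type in both crosses. A strain variant passed on by either parent predicts that the levels in the crosses sum to the wild-type level, and the median sum was 101% (quartiles 82.5% and 151%). The same is predicted by a dose effect of Anp32e, which stays open. An origin in the egg alone can give such a sum too: ENSDARG00000101370 stood at 0% of wild type in the maternal and 101% in the paternal cross. Loss of Anp32e from the egg as the whole cause is argued against, since 67.5% of them (27) held 20% or more of the wild-type level in maternal null embryos. For the other 13, all at 50% or more in paternal null embryos and 9 of them the chromosome 20 transcripts above, an origin in the egg stays open.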
